A study of Gallus gallus with 18 samples.

How the data were processed

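Liver RNA of broiler chickens was measured on 18 single-colour Affymetrix arrays with biotin-labelled target. The labels place the arrays in 3 diet groups of 6, which received 0, 7.5 or 15% of partially defatted larvae meal of the black soldier fly (Hermetia illucens, HI), equal to 0, 75 and 150 g per kg of diet, for 35 d. The groups are called HI0, HI7.5 and HI15. The trial held 72 male Cobb broilers in cages of 4. The labels do not say which cage each sample came from or that each array is a different bird, so the p-values measure the spread between these samples. Replicate numbers follow the order of deposit, and the labels name nothing shared by samples of the same number. The last numbers of the titles of such samples do fall in the same run of 6 numbers. A shared cage, place or day is therefore possible, and the main fit holds no term for it.

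The deposited values are log2 signals per probe set made by the authors with RMA in Affymetrix Expression Console 1.4, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a set, so small differences in total RNA or in overall brightness are already removed. The table holds 18226 probe sets without missing values, given to 2 decimals. Scanner files were not used here. The table gives no background or detection values, so no probe set was left out as dim. Array medians lay between 7.23 and 7.31, and no 2 arrays were identical. The number of arrays limits the precision.

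Probe sets were named from the platform annotation supplied with the values. It lists 12556 of the probe sets, of which 12300 have 1 gene symbol and 256 have several; 5670 are unnamed here. Of those with 1 symbol, 11727 were matched by gene identifier to the RefSeq gene table of assembly GRCg7b, and 0 symbols had to be updated. Only probe sets with 1 symbol were named. The probe set with the highest mean over all arrays stood for its gene, which left 11528 genes, 651 of them with more than 1 probe set.

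Each probe set was fitted with 1 mean per diet over all 18 arrays in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, default prior, 15 residual degrees of freedom before moderation). The comparisons were HI15 with HI0, HI7.5 with HI0 and HI15 with HI7.5, a moderated F test among the diets and a linear slope per 10 percentage points of meal. P-values are two-sided and were adjusted by Benjamini-Hochberg over all probe sets, with calls at 0.05. Differences are log2 values with the standard error (SE) of the fit. Gene lists, 27 of liver processes and 11 of cell types, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of 1343 listed symbols, 899 were measured, and 4 further lists were matched by symbol pattern. Lists were tested with camera at a preset inter-gene correlation of 0.01 on the gene table, adjusted over the 38 lists. The same lists were tested with camera at an estimated correlation, with fry, and by an exact permutation of the list mean per sample over all 924 splits of 6 against 6. The covariance of the meal diets' differences was first computed over all probe sets, and after that value was seen it was changed to the 11528 genes, as the plan states.

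Genes were named by a fixed rule. Genes past the threshold were to be named first, up to 10 in each direction. Where none passed, the 5 smallest unadjusted p-values in each direction were taken for HI15 against HI0, 3 for the other comparisons and 5 for the slope. Each list past the camera threshold contributed the 4 members with the smallest p in its direction, and other lists described contributed 2; which of those lists to describe was chosen after their values were seen. Any gene named outside this rule is marked as chosen after its values were seen.

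The fit was tested on simulated data with the measured means and spreads and 200 changed probe sets among 18226. For HI15 against HI0 it recovered 26.6% of 1.3-fold, 62.4% of 1.5-fold, 96.2% of 2-fold and 99.0% of 3-fold changes, with 4.50% false calls. For HI7.5 against HI0 it recovered 23.2, 65.8, 92.4 and 98.8% of these, with 5.20% false calls. Changes of all these sizes were planted together, so the larger ones eased the adjusted threshold for the smaller. Recovery of small changes would be lower where few large ones are present. Camera, tested on 11528 independent simulated genes for HI15 against HI0, gave p below 0.05 for 4% of 100 unchanged lists of 20 genes and for 100% of lists shifted by 0.2. The number of simulated lists was raised to 100 after the result of a first, smaller run had been seen. Neither simulation holds correlation between genes, so the 4% does not apply to lists of correlated genes.

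Alternatives were quantile normalization, subtraction of array medians, only probe sets above the median level, a variance trend with a robust prior, array weights, the last number of each title as a covariate (its meaning is not stated), fits of only the 2 groups compared, other thresholds and tests, and the omission of each array in turn. The spread of each array's log2 values as a covariate, a block by runs of that last number and the omission of 2 arrays were added after the data were seen. No coordinates are given, because the genome build behind the array annotation is not given in the sources used here.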

Results

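The study asked how replacing soybean meal with insect meal affects the liver transcriptome of broilers. Liver samples were compared between birds fed no meal of black soldier fly larvae (HI0) and birds fed 7.5% (HI7.5) or 15% (HI15) for 35 d, with 6 arrays per diet. The log2 signals ran from 1.00 to 15.1. Arrays correlated with each other at 0.966 to 0.990, and the median correlation was 0.983 within a diet and 0.982 between diets. HINTW, a gene of the female-specific W chromosome, lay between 5.47 and 6.42 on every array, and no array stood apart from the others. Without a female sample or a background value, its level alone does not test the male label.

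The comparison of HI15 with HI0 gives the effect of the higher inclusion level. No single gene passed the test, and the list test called small shifts of 8 gene groups. Of 100 splits of these 12 samples, the real one included, 67 gave at least as many called lists. The number of lists called therefore does not set the real grouping apart. Genes of cholesterol synthesis and uptake were lower, by a median of -0.22 over 18 measured members, and 15 of the 18 were below 0. Genes of oxidative phosphorylation (median 0.10, 49 of 54 above 0) and of amino acid catabolism (median 0.10, 43 of 54 above 0) were higher. Smaller upward shifts were measured for the proteasome, cytosolic ribosomal proteins, translation factors with aminoacyl-tRNA synthetases, and purine synthesis. Markers of pancreas and gut, which are not liver genes, were lower (median -0.09). These list shifts passed camera only at its preset inter-gene correlation, and each call was lost with an estimated correlation (adjusted p = 0.802 for each of the 8). The estimated correlation of the 8 lists ran from 0.05 for purine synthesis to 0.41 for oxidative phosphorylation, against the preset 0.01. A preset below the correlation within a list makes its camera p too small.

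The cholesterol list had the largest shift and a camera adjusted p of 1.53e-05 in HI15 against HI0. With an estimated correlation its p was 0.0454 before and 0.802 after adjustment. At an unadjusted p under 0.05, 5 members were lower and 2 higher, INSIG2 at 0.29 and ACAT2 at 0.30, both chosen after their values were seen. The lower members with the smallest p were STARD4, which carries sterols between membranes, at -0.73 ± 0.25 (SE), and INSIG1, which retains the sterol sensor in the endoplasmic reticulum, at -0.43 ± 0.15. NSDHL, a late enzyme of the pathway, was at -0.41 ± 0.16, and FDFT1, squalene synthase, at -0.63 ± 0.27. None of these passed adjustment. Leaving out each sample in turn took the list mean from -0.22 to between -0.28 and -0.14. The list mean per sample was -0.22 ± 0.24 (SD) relative to HI0 in HI15 and 0.00 ± 0.16 in HI0. An exact permutation of those means gave p = 0.0909 before and 0.991 after adjustment over all lists.

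Lists of nitrogen metabolism were higher in HI15 than in HI0. The amino acid catabolism list had a camera adjusted p of 0.000265 at the preset correlation and 0.802 with an estimated correlation. Without HI0 replicate 5 its mean difference went from 0.11 to 0.06 and the call was lost (adjusted p = 0.0691), as it was without the 2 samples at the ends of the first principal component (0.0538). Without HI15 replicate 6 its mean was 0.17. Its leading members were UROC1 of histidine breakdown at 0.41 ± 0.18 (SE), HGD of tyrosine breakdown at 0.23 ± 0.10, AGXT2 at 0.47 ± 0.25 and ornithine aminotransferase, OAT, at 0.28 ± 0.15. In birds purine synthesis carries surplus nitrogen into uric acid, and 14 of the 21 genes of that list were above 0 (median 0.09, camera adjusted p = 0.0407; p = 0.0600 before and 0.802 after adjustment with an estimated correlation). PPAT, which catalyses the first committed step of purine synthesis, was at 0.42 ± 0.15, and PAICS at 0.52 ± 0.17. GLUL, glutamine synthetase, was at 0.49 ± 0.18 and ADA, adenosine deaminase, at 0.17 ± 0.09. All 6 HI15 samples lay above the HI0 mean for each of PPAT, PAICS, GLUL and ADA, yet none passed adjustment. At an unadjusted p under 0.05, 3 members of the purine list were higher and 1 was lower. The purine call was lost in 7 of 18 omissions of a sample, after quantile normalization (adjusted p = 0.271), with the array spread as a covariate (0.134) and without the 2 end samples (0.167).

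Oxidative phosphorylation and 3 lists of protein turnover were also higher. Oxidative phosphorylation had a camera adjusted p of 3.16e-06 and 0.802 with an estimated correlation, with no member at an unadjusted p under 0.05. Its mean difference of 0.10 depended on HI0 replicate 5, which lay at -0.24 while the other HI0 samples lay between 0.01 and 0.07; without that sample the mean was 0.05 (camera adjusted p = 0.0124), and without HI15 replicate 6 it was 0.15. Its leading members were NDUFB6 at 0.23, ATP5H at 0.21, SDHB at 0.17 and NDUFA9 at 0.16. The proteasome list had 25 of 29 members above 0, led by PSMB3 at 0.21, PSMD5 at 0.16, PSMA4 at 0.15 and PSMD14 at 0.13 (camera adjusted p = 0.00778). Cytosolic ribosomal proteins had 42 of 53 above 0, with RPL37 at 0.14, RPS29 at 0.16, RPL39L at 0.13 and RPL14 at 0.15 (0.0179). The translation list had 44 of 63 above 0, with EIF4EBP2 at 0.20, EIF2S1 at 0.14, EEF2K at 0.24 and RARS at 0.18 (0.0232). With an estimated correlation the adjusted p was 0.802 for these lists too. The proteasome call was also lost without HI0 replicate 5, where its mean went from 0.06 to 0.03. The ribosomal call was lost in 5 of 18 omissions of a sample (mean from 0.05 to between 0.02 and 0.09) and the translation call in 3 (0.05 to between 0.03 and 0.07). The proteasome, ribosomal and translation calls were lost after quantile normalization (adjusted p = 0.197, 0.577 and 0.351) and with the array spread as a covariate (0.107, 0.134 and 0.305). Without the 2 end samples the proteasome and translation calls were lost too (0.171 and 0.167).

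**Figure D1:**
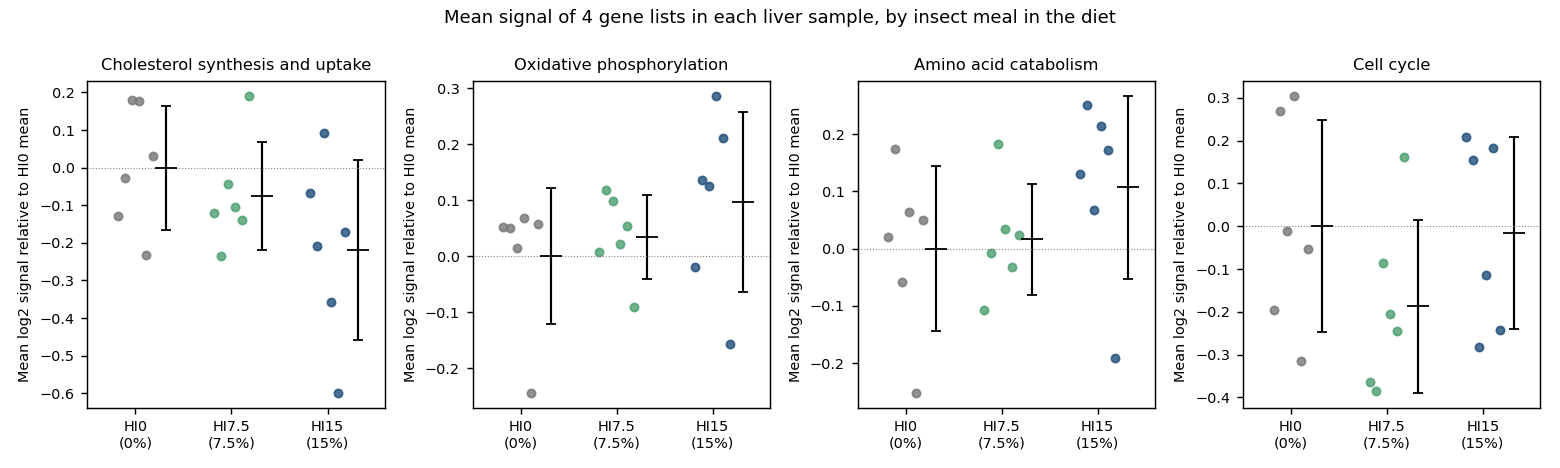
Mean log2 signal of the genes of 4 lists in each liver sample, relative to the HI0 mean (vertical axis), for the 3 diets; points are samples and bars are the mean ± SD of 6. In HI15 the cholesterol list ranges from -0.60 to 0.09, against -0.23 to 0.18 in HI0, and the diets overlap in every panel.

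The lists described here and below that did not pass were chosen after their values were seen. Ranges give the list mean when each sample was left out in turn. In every one of the 14 lists of HI15 against HI0, 11 of HI7.5 against HI0 and 5 of HI15 against HI7.5 some omission moved the mean by over 1.5 times, and it turned the sign in 6, 7 and 2 of them. Of these lists, 8, 5 and 2 were called in at least 1 omission. Among the lists that passed, some omission moved the mean as far in 7 of 8, 1 of 2 and 7 of 10, with 0 turns of sign. In HI15 against HI0, xenobiotic metabolism held CYP1A1 at 0.58 ± 0.20 (SE) and CYP1A2 at 0.62 ± 0.21, enzymes induced through the aryl hydrocarbon receptor (list median 0.05, camera adjusted p = 0.0894; range 0.02 to 0.11). In the interferon-stimulated list, DDX60 was at 1.56 ± 0.49 and CMPK2 at 0.35 ± 0.16 (median 0.04, adjusted p = 0.147; range 0.05 to 0.15). The antioxidant list held GPX4 at 0.32 and SOD1, superoxide dismutase, at -0.25 (0.0911; range 0.01 to 0.06). The acute phase list held AVD, avidin, at -0.49 and TLR1B at -0.38 (0.453; range -0.04 to 0.02). In phospholipid metabolism CERS6, a ceramide synthase, was at 0.80 and CDS1 at 0.32 (0.121; range 0.03 to 0.07). Fatty acid and triglyceride synthesis had a median of -0.03 (0.813; range -0.07 to 0.00), with HACD2 at 0.20 and AGPAT2 at 0.20. Fatty acid oxidation had a median of 0.06 (0.121; range -0.04 to 0.07), with ACOT12 at -0.35 and ACSM4 at -0.38. For bile acid synthesis and transport the median of 0.01 and the mean of -0.01 differed in sign (0.904; range -0.05 to 0.05), with ABCC2 at 0.12 and CYP7B1 at 0.17. The chitin and glycan hydrolase list also had a median of 0.03 beside a mean of 0.00 with a negative sign (0.598; range -0.03 to 0.03), with GNPDA2 at 0.10 and LYZ, lysozyme, at 0.13.

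**Figure D2:**
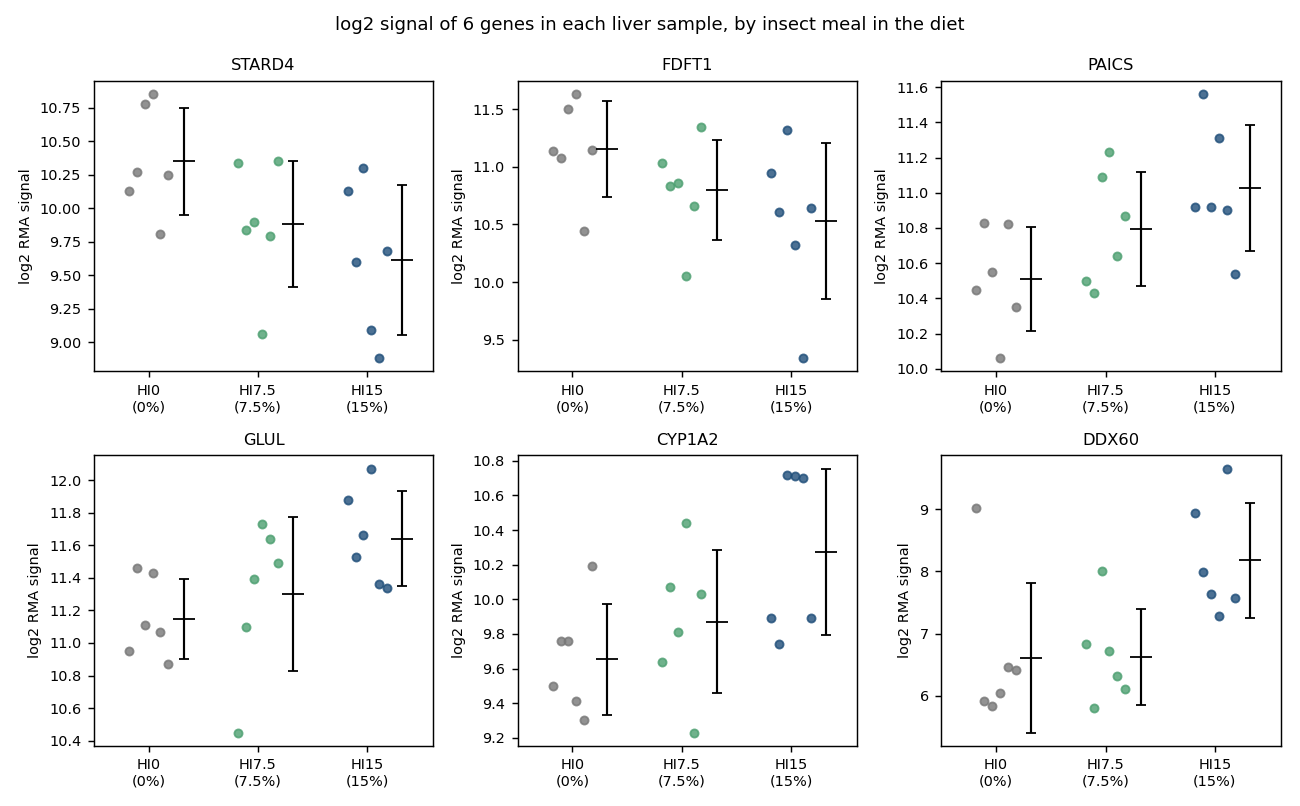
log2 RMA signal (vertical axis) of 6 genes in each liver sample for the 3 diets; points are samples and bars are the mean ± SD of 6. DDX60 lies between 7.28 and 9.65 in HI15, while 1 HI0 sample reaches 9.01 and the other HI0 samples stay at or below 6.46.

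The higher genes with the smallest p in HI15 against HI0 were TFRC, the transferrin receptor, at 0.52 ± 0.14 (SE), RIDA at 0.49 ± 0.14, POC1A at 0.36 ± 0.10, KCNK7 at 0.47 ± 0.14 and GYG2, a glycogenin, at 0.46 ± 0.14. Their unadjusted p-values ran from 0.00156 to 0.00322. The 2 probe sets of TFRC differed in sign, and the dimmer one was at -0.13. TFRC was also the single member of the iron, copper, zinc and selenium list, and of any list in any comparison, that passed when adjusted over the list alone (adjusted p = 0.0313). SLC40A1, ferroportin, of that list was at -0.14, and the list's camera adjusted p was 0.246 (range 0.02 to 0.07). The lower genes were KCNG2 at -0.36 ± 0.09, OTOG at -0.44 ± 0.11, GADL1 at -0.40 ± 0.10, the microRNA gene MIR193A at -0.39 ± 0.11 and LOC422147 at -0.40 ± 0.11, with p from 0.000837 to 0.00166. The smallest adjusted p of any probe set was 0.892, for the dimmer of 2 probe sets of PRMT1, an arginine methyltransferase, at 0.61; it was chosen after its values were seen, and the brighter one was at 0.22.

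With limma, 0 probe sets passed in HI15 against HI0. At an unadjusted p under 0.05 there were 573, against 911.3 expected on average if nothing differed. Random splits of the same 12 samples gave a median of 576, so 573 was not a deficit for these samples. The 95% confidence interval of the difference lay within 1.5-fold either way for 91.4% of probe sets and within 2-fold for 99.1%. Dim probe sets are included in these shares. Taken 1 probe set at a time, these unadjusted intervals left out signal changes of over 1.5-fold for most of the array. For dim probe sets this does not exclude a change in RNA. Narrower limits were not counted, and the median half-width of the interval was 0.257 in log2. Fry and the exact permutation of list means called 0 lists.

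The comparison of HI7.5 with HI0 gives the effect of the lower inclusion level. Cell cycle genes were lower as a group, with a median of -0.21 over 59 members and 55 of them below 0 (camera adjusted p = 2.42e-11). With an estimated correlation, 0.42 for this list, their adjusted p was 0.904, and the exact permutation of the list mean per sample gave p = 0.175. The mitotic genes AURKB at -0.48 ± 0.19 (SE), TPX2 at -0.38 ± 0.16, CDC20 at -0.28 ± 0.13 and BIRC5 at -0.28 ± 0.11 led the list. In HI15 against HI0 the same list had a median of -0.04 and did not pass (adjusted p = 0.425; range -0.08 to 0.05), with BUB3 at 0.33 and BIRC5 at -0.23.

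None of the metabolic lists passed in HI7.5 against HI0. The cholesterol list had a median of -0.13, with ACAT2 at 0.38 and INSIG2 at 0.28 as its members with the smallest p (camera adjusted p = 0.341; range -0.13 to -0.04). Purine synthesis had a median of 0.09, with ADSL at 0.26 and PAICS at 0.28 (0.112; range 0.04 to 0.10). Oxidative phosphorylation had a median of 0.03, with NDUFA9 at 0.17 and NDUFV2 at 0.13 (0.112; range -0.01 to 0.06); the other NDUFV2 probe set had the opposite sign. The amino acid shortage list had a median of 0.06, with PSAT1 of serine synthesis at 0.43 and the amino acid transporter SLC7A5 at 0.24 (0.112; range 0.03 to 0.12). Amino acid catabolism had a median of 0.02, with the urea cycle gene ASS1 at -0.52 and ASPA at -0.30 (0.604; range -0.03 to 0.05). The interferon-stimulated list had a median of -0.04, with GBP4L at -0.27 and MX1 at -0.22 (0.213; range -0.08 to 0.02). Without HI0 replicate 4, GBP4L was at -0.17 and INSIG2 at 0.19. The acute phase list had a median of 0.01, with AVD at -0.39 and IL1R2 at 0.47 (0.754; range -0.02 to 0.04). For fatty acid and triglyceride synthesis the median of -0.01 differed in sign from the test (0.957; range -0.04 to 0.03), with HACD2 at 0.26 and MID1IP1 at -0.09.

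The single genes with the smallest p in HI7.5 against HI0 were TM4SF4 at 0.35 ± 0.09 (SE), TLE1 at 0.36 ± 0.10 and PSAT1 at 0.43 ± 0.12 among the higher, and the microRNA gene MIR34B at -0.86 ± 0.19, CDCP1 at -0.42 ± 0.10 and IMMP2L at -0.47 ± 0.13 among the lower. With limma 0 probe sets passed, the smallest adjusted p was 0.999, and 565 had an unadjusted p under 0.05. The 95% interval lay within 1.5-fold for 91.2% of probe sets.

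The comparison of HI15 with HI7.5 asks whether the inclusion levels differ. Cell cycle genes were higher in HI15 (median 0.16, 53 of 59 above 0, camera adjusted p = 5.03e-08), with CDC25A at 0.29, CENPN at 0.33, MAD2L1 at 0.22 and RRM2 at 0.63. Interferon-stimulated genes were higher (median 0.07, adjusted p = 0.00152), led by DDX60 at 1.54 ± 0.49 (SE), ZC3HAV1 at 0.31, CMPK2 at 0.34 and the RNA sensor IFIH1 at 0.21. The cholesterol list was lower (median -0.12, adjusted p = 0.00152), led by HMGCS1 at -0.51, SCAP at -0.34, INSIG1 at -0.28 and NSDHL at -0.24. With an estimated correlation the adjusted p was 0.890 for each of these 3 lists. The cholesterol call was lost in 2 of 18 omissions, and omissions took its mean from -0.14 to between -0.20 and -0.07, the latter without HI15 replicate 5. The interferon call was lost without HI7.5 replicate 1 (adjusted p = 0.0707). The exact permutation of list means gave unadjusted p = 0.197, 0.0325 and 0.245 for them, and 0 lists passed after adjustment.

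Further lists were higher in HI15 than in HI7.5 at the preset correlation. They were cytosolic ribosomal proteins (median 0.06; RPS29 at 0.26, RPS28 at 0.20, RPL23 at 0.16 with its other probe set opposite in sign, RPS3 at 0.14; camera adjusted p = 0.00113) and amino acid catabolism (median 0.08; UROC1 at 0.47, ASS1 at 0.54, GSTZ1 at 0.25, GOT1 at 0.16; 0.00205). Stellate cell and fibroblast markers were higher too (median 0.11; LUM, lumican, at 0.47, LRAT at 0.34, RGS5 at 0.43, PDGFRA at 0.29; 0.0111). Oxidative phosphorylation had a median of 0.05 (NDUFA7 at 0.29, ATP5H at 0.18, NDUFA1 at 0.19, NDUFB9 at 0.18; 0.0129). Fatty acid oxidation had a median of 0.08 (HACL1 at 0.24, PPARGC1A at 0.34, PDK4 at 0.53, ACAA2 at 0.17; 0.0214). Immediate early genes were lower (median -0.08; KLF6 at -0.35, EGR1 at -0.73, NR4A3 at -0.49, SGK1 at -0.40; 0.0147), as were heat shock genes (median -0.08; HSPH1 at -0.28, HSPA4L at -0.21, HSPA8 at -0.13, DNAJA1 at -0.16; 0.0454). With an estimated correlation the adjusted p was 0.899 for oxidative phosphorylation and 0.890 for the other lists of this paragraph. Omitting 1 of the 18 samples ended the call of fatty acid oxidation in 6 cases, heat shock in 6, oxidative phosphorylation in 4, immediate early genes in 4, stellate cells in 3, ribosomal proteins in 2 and amino acid catabolism in 1. Omissions took the mean of the stellate list from 0.13 to between 0.05 and 0.18, amino acid catabolism from 0.09 to between 0.06 and 0.15, and oxidative phosphorylation from 0.06 to between 0.02 and 0.11. Fatty acid oxidation went from 0.07 to between 0.03 and 0.10, ribosomal proteins from 0.06 to between 0.03 and 0.10, and heat shock from -0.07 to between -0.10 and -0.04. Without HI7.5 replicate 4, NR4A3 was at -0.24. The heat shock call was also lost after quantile normalization (adjusted p = 0.0882), with the array spread as a covariate (0.147) and without the 2 end samples (0.32).

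Lists that did not pass between the inclusion levels included the amino acid shortage list, with SLC38A2 at -0.47 and STC2 at 0.49 (camera adjusted p = 0.506; range -0.07 to 0.03), and endoplasmic reticulum protein folding, with ERN1 at -0.37 and HERPUD1 at -0.24 (0.506; range -0.08 to 0.05). The antioxidant list held NFE2L2, the gene of NRF2, at 0.23 and GCLM at 0.23 (0.323; range 0.02 to 0.04), and the acute phase list held IL8L1 at -0.27 and AvBD10 at 0.41 (0.299; range -0.04 to 0.00). The single genes with the smallest p were FAM110B at 0.39 ± 0.08 (SE), the scavenging chemokine receptor ACKR4 at 0.96 ± 0.21 and OLFML1 at 0.70 ± 0.19 among the higher. Among the lower they were KCNG2 at -0.38 ± 0.09, the kinase gene SIK1 at -0.99 ± 0.28 and SLC45A3 at -0.27 ± 0.08, whose other probe set had the opposite sign. With limma 0 probe sets passed, the smallest adjusted p was 0.832, and 576 had an unadjusted p under 0.05. The 95% interval lay within 1.5-fold for 91.3% of probe sets.

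Across the 3 diets together, 0 probe sets passed the F test (smallest adjusted p = 0.807, 523 at an unadjusted p under 0.05) and 0 passed for a linear slope over meal percentage (smallest adjusted p = 0.999, 592 at an unadjusted p under 0.05). With equal groups at evenly spaced levels, the HI7.5 mean cancels out of the slope. Each slope is therefore the HI15 against HI0 difference rescaled, and it gives no separate evidence of a trend with dose. The slopes with the smallest p, per 10 percentage points of meal, were TFRC at 0.35, RIDA at 0.33, POC1A at 0.24, KCNK7 at 0.31 and GYG2 at 0.31. In the other direction they were OTOG at -0.29, MIR193A at -0.26, GADL1 at -0.27, LOC422147 at -0.27 and RAB38 at -0.42.

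The differences of the 2 meal diets from HI0 were compared over 11528 genes, which are not independent replicates. They correlated at 0.50 with a covariance of 0.00817. Both comparisons use the same HI0 samples, and 100 simulated sets of unchanged groups against shared controls gave a mean correlation of 0.482 and a mean covariance of 0.0103, so the observed covariance differed from that of no effect by -0.00212. When the HI0 samples were split 3 and 3 between the comparisons, the mean correlation over 20 splits was -0.06, within a range of -0.35 to 0.06. No shared effect of the inclusion levels was detectable.

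Markers of cell types were compared to see whether the make-up of the liver pieces followed the diets. Pancreas and gut markers were lower than in HI0 by a median of -0.09 in HI15 (camera adjusted p = 0.0201; CPB1 at -0.21, PNLIPRP1 at -0.25, CEL at -0.20, FABP2 at -0.24) and of -0.08 in HI7.5 (0.0147; FABP2 at -0.48, PRSS3 at -0.32, CUZD1 at -0.41, GUCA2B at -0.19). With an estimated correlation their adjusted p was 0.802 and 0.904. The mean of this list followed the first principal component (r = -0.914), and both calls were lost with the array spread as a covariate (adjusted p = 0.304 and 0.953), after quantile normalization (0.197 and 0.304) and without the 2 end samples (0.143 and 0.803). Omitting single samples ended the HI15 call in 3 of 18 cases (mean from -0.07 to between -0.10 and -0.04) and the HI7.5 call in 5 (-0.10 to between -0.14 and -0.06). Some of these genes were dim, such as CPB1 at 5.12 and FABP2 at 4.35 in HI0. Probe sets of PRSS3 and of CUZD1 disagreed in sign in HI7.5. Red blood cell markers had a median of 0.14 in HI15, with EPB41 at 0.24 and CA2, carbonic anhydrase, at 0.26 (0.0632; range 0.03 to 0.17). HI15 replicate 6 carried much of this: without it the list mean went from 0.11 to 0.03 and CA2 to 0.12. T and NK cell markers had a median of -0.07 in HI15, with GZMA at 0.44 and CD247 at -0.22 (0.183; range -0.08 to 0.04), and of -0.06 in HI7.5, with CTLA4 at -0.28 and LCK at -0.33 (0.492; range -0.07 to 0.05). Macrophage and Kupffer cell markers had a median of 0.10 in HI7.5, with MRC1 at 0.40 and LY86 at 0.28 (0.129; range 0.04 to 0.19), and of -0.08 in HI15 against HI7.5, with SLC40A1 at -0.18 and LY86 at -0.28 (0.0547; range -0.16 to -0.03). Bile duct markers had a median of -0.04 in HI7.5, with CLDN10 at 0.42 and KRT24 at -0.36 (0.959; range -0.04 to 0.06). Hepatocyte markers had a median of 0.02 in HI15, with SERPINC1 at 0.13 and APOH at 0.06 (0.557; range 0.00 to 0.04). By exact permutation of the marker mean per sample, 0 of the 11 cell type lists differed in any comparison.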

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

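The tests of quantile normalization, of array spread, single samples and diet for the cholesterol list, of a gene variant, and the splits for called probe sets were chosen only after the result was seen. The limits set for the array spread and single-sample tests were written with the values known. Single samples stood apart from the other 5 of their diet in 28 of the 552 sets of values examined (146 genes and 38 list means in 3 diets), where chance gives about 27.6. HI0 replicate 5 held more of the 28 than any other sample. The sets share samples and genes, so the total does not test chance.

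The first principal component, 23.2% of the variance, orders the samples from HI0 replicate 5 to HI7.5 replicate 3. It followed the standard deviation of each array's log2 values (Pearson r = 0.963, Spearman rho = 0.953, permutation p = 1e-05 for both, the smallest the resamples can give, adjusted 6e-05 over 6 relations; r = 0.937 without these 2 samples). The axis found after quantile normalization correlated at 0.986 with it and held 18.1% of the variance. The correlation argues against the overall distribution of values as the whole cause. With the lower share, a part from that distribution remains possible. Diet accounted for 5.60% of it (permutation p = 0.643), too little to be its main source. The mean level of a probe set accounted for 25.8% of the loadings, so a signal-level dependent array effect, from labelling or RNA quality for example, remains possible and cannot be told apart from a difference between birds. Besides pancreas and gut markers, other list means followed the axis. They include phospholipid metabolism (r = 0.922), iron, copper, zinc and selenium handling (0.871), the translation list (0.760) and the proteasome (0.706).

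The cholesterol list was lower in HI15 than in HI0 by a mean of -0.22 (unadjusted 95% interval -0.45 to 0.01). With the array spread as a covariate it was -0.21, which argues against that spread as the cause. Without HI15 replicate 5 it was -0.14, the value nearest to 0 among the 12 omissions, so that sample contributes much of the shift but not all of it. Diet may lower these genes, but the exact permutation p of 0.0909, which is unadjusted, leaves chance between samples open. Adjusted over all lists tested, that permutation p was 0.991. Effects of diet and of chance cannot be told apart with these samples.

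CYP2C45, a cytochrome P450 gene, was at 6.43 in HI7.5 replicate 4 and at 6.84 in HI15 replicate 1, while the other 16 samples lay between 10.5 and 13.4. It was chosen after its values were seen. A failure of these 2 arrays is argued against, since 0 other probe sets had the same 2 samples lowest by at least 1 in log2, and no other pair of arrays had more than 1. An inherited variant of the gene or of the sequence under its probes may lie behind it; the count of 0 permits that, but it cannot be told apart from low expression of the gene for another reason, because no second probe set was measured.

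In HI0, replicate 5 had the lowest values of the lists of oxidative phosphorylation (-0.24 relative to the HI0 mean), fatty acid oxidation (-0.36), proteasome (-0.16) and antioxidant genes (-0.15), and of ATP5H (9.52), NDUFA1 (8.28), NDUFB6 (7.92), GOT1 (9.79), RPS3 (10.3) and SCAP (10.1). HI0 replicate 4 was highest for T and NK cell markers (0.37) and GBP4L (9.39) and lowest for INSIG2 (9.88). HI0 replicate 6 was highest for bile acid genes (0.29), HI0 replicate 3 for ACAT2 (10.1), and HI0 replicate 1 for DDX60 (9.01, the others at most 6.46).

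In HI7.5, replicate 4 was lowest for CYP2C45 (6.43) and RPL37 (11.2) and highest for NR4A3 (7.80) and PPARGC1A (8.88). HI7.5 replicate 3 was highest for HGD (11.1), replicate 1 for RPS29 (11.1), and replicate 5 was lowest for xenobiotic metabolism (-0.23). In HI15, replicate 6 was highest for AvBD10 (12.5) and CA2 (10.1) and lowest for SLC7A5 (8.49). HI15 replicate 5 was highest for NDUFA9 (10.2) and replicate 3 for RPL39L (12.3).

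For the 0 probe sets called in each pairwise comparison, in the F test and for the slope, splits test nothing, since every one of the 100 reaches a count of 0. The highest count of another split was 1 for HI15 against HI0, 2 for HI7.5 against HI0, 73 for HI15 against HI7.5, 14 for the F test and 0 for the slope. Of 100 splits of the 12 samples, 67 gave at least the 8 lists of HI15 against HI0 (highest other 19), 99 the 2 lists of HI7.5 against HI0 (highest other 17), and 33 the 10 lists of HI15 against HI7.5 (highest other 16). The median number of lists in the other splits was 10, 9 and 8. At an unadjusted p under 0.05, 51, 75 and 67 of 100 splits gave as many probe sets as the real 573, 565 and 576. The medians of the other splits were 576, 850 and 683, and the highest were 2545, 4795 and 5054. Chance cannot be excluded for these counts of lists or of probe sets at an unadjusted p. Splits with several times the real count point to structure among the samples that the diets do not follow.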

How the results depend on the processing

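The array spread covariate, the replicate block and the omission of the 2 samples at the ends of the first principal component were chosen after seeing the data. Of 147 recomputed counts of changed probe sets, all but 3 were 0, whatever the adjusted threshold, normalization, filter, covariate or omission. The 3, at an unadjusted p under 0.05 with a fold of at least 1.3, were 150 for HI15 against HI0, 164 for HI7.5 against HI0 and 175 for HI15 against HI7.5. The number of lists called was less stable. With the correlation estimated per list, or with fry, it was 0 in each comparison. The estimated correlations of the 8 lists called for HI15 against HI0, 0.05 to 0.41, lay above the preset 0.01. The cause of the changes in the number of lists under the other settings was not tested. For HI15 against HI0 the number of lists fell from 8 to 3 after quantile normalization, 4 with probe sets above the median level and 4 with the array spread as covariate. For HI7.5 against HI0 it went from 2 to 4 with probe sets above the median level, 1 with array weights and 1 with the array spread. Omitting single samples gave 7 to 16 lists for HI15 against HI0 (16 without HI0 replicate 1 or replicate 6, 13 without HI15 replicate 4). It gave 1 to 7 for HI7.5 against HI0 (5 without HI0 replicate 4, 4 without HI0 replicate 5, 1, 4, 5 and 7 without HI7.5 replicates 3, 4, 5 and 6), and 3 to 11 for HI15 against HI7.5 (6 and 3 without HI15 replicates 4 and 5). The covariance of the meal diets' differences moved by less than the standard deviation of its simulated values, 0.00576, under every alternative. By exact permutation, 0 cell type lists differed with brighter markers too. Of 7544 recomputed values of named genes, 7542 kept their sign. PLIN1 in HI7.5 against HI0 reversed to 0.0363 with the array spread as covariate and to 0.048 without the 2 end samples. The lowest adjusted p of any named gene was 0.233. The last title numbers fall into 6 runs of 6 numbers, each with 1 sample per diet, and the samples of a run have the same replicate number. Deviations from the diet means correlated above 0.1 in 5 of 18 pairs within a run (median -0.0812), and 1 of 18 samples correlated best with its own run. No effect of the run was visible, which does not exclude that samples of a run share something besides a number. With the run as a replicate block there were 0 probe sets and 8, 2 and 11 lists for HI15 against HI0, HI7.5 against HI0 and HI15 against HI7.5. Signal over background is not given in the table used, so its effect on dim probe sets is unknown.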

Other observations

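Beyond diet, single genes differed widely between liver samples. The median standard deviation of a gene over the 18 samples was 0.205, against 1.09 to 1.25 for ANGPTL4, PCK1 and DIO2. The genes of this part were chosen after their values were seen. ANGPTL4, an inhibitor of lipoprotein lipase, ranged from 7.37 to 11.7, PCK1 of gluconeogenesis from 7.14 to 11.2, and DIO2, which activates thyroid hormone, from 6.83 to 10.6. Of their variance, 5.16%, 13.7% and 16.6% lay between the diets. Diet groups also differ by chance, so these shares do not measure an effect of diet. BF2, a class I gene of the major histocompatibility complex, ranged from 7.49 to 11.4, with 4.67% of its variance between diets. CA4, a carbonic anhydrase, ranged from 6.21 to 10.9 with 0.0605% between diets.

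Among the most variable genes DDX60 had the largest share between diets, 40.1% of its variance. ETNPPL at 26.6%, WDPCP at 20.5% and CYP2C45 at 18.7% came next. Some share between diets arises by chance too, and its expected size was not computed. For DDX60, all 6 HI15 samples lay at or above 7.28, while HI0 held 1 sample at 9.01 and HI7.5 1 at 8.0. The adjusted p of DDX60 in limma did not pass in any comparison.

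The 6 relations were chosen after the data were seen. Across the 18 samples, the list means of amino acid catabolism and oxidative phosphorylation correlated (Pearson r = 0.787, permutation p = 0.00014, adjusted 0.00042; Spearman rho = 0.697, permutation p = 0.00187, adjusted 0.00561, over 6 relations). The value was r = 0.762 within diets and r = 0.566 without the 2 samples farthest from the median, HI0 replicate 5 and HI15 replicate 6. T and NK cell markers and interferon-stimulated genes had r = 0.516 (permutation p = 0.0270, adjusted 0.0541) and rho = 0.375 (permutation p = 0.127, adjusted 0.230). For them r was 0.583 within diets but 0.230 without HI0 replicates 4 and 6, so this relation rests largely on those samples. T and NK cell markers and cell cycle genes had r = 0.456 (permutation p = 0.0517, adjusted 0.0775) and rho = 0.350 (permutation p = 0.153, adjusted 0.230), with r = 0.32 without the same samples. The cholesterol list and fatty acid synthesis were not detectably related (r = 0.168, permutation p = 0.507, adjusted 0.507; rho = 0.302, permutation p = 0.220, adjusted 0.264), nor were immediate early and heat shock genes (r = 0.336, permutation p = 0.170, adjusted 0.205; rho = 0.253, permutation p = 0.309, adjusted 0.309).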
